A study of Homo sapiens with 6 samples.

How the data were processed

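RNA of K562 cells, an established human chronic myelogenous leukemia line, was measured in 6 libraries. Per the labels, cells received either siRNA against HNRNPU at 300 nM or control oligos. Whole-cell, nuclear and cytosolic RNA was then taken from each condition, which gives 6 groups of 1 library. Per the labels' protocols, RNA was extracted with TRIzol, ribosomal RNA was depleted and strand-specific libraries were sequenced on an Illumina HiSeq X-10 instrument. Whether the 3 preparations of a condition came from a single culture is not given in the sources used here.

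The authors deposited FPKM values, which are fragments per kilobase of transcript scaled to the size of the library, 1 column per library, over 62828 loci. The unit was read from the values and from the tools, because no header names it. The submitters' processing notes name CASAVA, FastQC, TopHat2 2.0.13 and Cuffdiff 2.2.1 and the builds hg19 and mm9, with no roles. The coordinates in the table are of hg19. The library scaling, the annotation and whether counting used the strand are not given in the sources used here. Antisense loci are therefore reported with the limit that fragments of the opposite gene could have been counted there. Neighbouring or overlapping genes can be merged into a single locus: 2058 of the loci kept carry several gene names.

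Loci on chromosome Y and the loci of XIST and TSIX (521 in all) were left out. Gene types came from GENCODE release 29 by gene symbol, and from RefSeq synonyms for older symbols. No coordinates of that annotation were used, since it is on another build. A locus counted as protein-coding if any of its names was. It counted as lncRNA if it had a lncRNA name and no protein-coding name: 244 of the lncRNA loci analysed carry a symbol of that release, and 60 an older symbol. Clone-based names, which annotation releases reuse, were kept as a class of their own (38.6% of the named loci), as were loci with no name.

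Loci with a mean of at least 1 FPKM over the 6 libraries were analysed (12824). Ratios are differences of log2(FPKM + 0.1), so they understate the change of low loci. The localization shift is the log2 ratio of nuclear to cytosolic FPKM after knockdown minus that in the control. A shift below 0 is toward the cytosol. With 1 library per group no test within a preparation is possible and no difference has a replicate check. A test of condition over the 3 preparations, with 2 libraries in each, was not run, since whether they came from separate cultures is not stated. Genes were therefore described by fixed rules of size (a log2 value of at least 1, which is 2-fold). Lists and classes were compared with 10000 random lists of the same size, matched on mean FPKM in 25 bins, and the percentile of the median is given as a description of these libraries. An interval of a median over loci is the 95% interval from binomial ranks. It covers the spread between loci, not between cultures.

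Before the data were examined, 36 gene lists, the comparisons and the rule for named genes were fixed. The rule takes, at a mean of at least 1 FPKM, the 8 lncRNA loci with the lowest and the 8 with the highest shift. At a mean of at least 5 FPKM it takes the 5 protein-coding loci with the lowest and the 5 with the highest shift. For whole-cell RNA it takes, at a mean of at least 5 FPKM and the same sign in all 3 preparations, the 8 protein-coding and 4 lncRNA loci with the largest ratios each way. Some genes that the rule picks are not named in the text. Up to 4 members are named per list, those with the largest changes. A further 10 genes were always to be named, of which 9 were found. FIRRE was not among the locus names and is not analysed here. A locus is called by its gene, and the other names of a merged locus are given for some loci only.

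FPKM carries depth in its low values, because single fragments give steps. The value of 1 fragment per kilobase was taken from the sharpest peak of low values over single-exon loci, with 220 bases taken off the length. It was 0.0430 FPKM in control and 0.0532 in knockdown whole-cell RNA, 0.0513 and 0.0255 in nuclear RNA, and 0.0746 and 0.0674 in cytosolic RNA. So 1 FPKM over 1 kilobase stands for about 23.3, 18.8, 19.5, 39.2, 13.4 and 14.9 fragments in the same order. Steps from pairs of low loci of any structure gave nearly the same relative depth: log2 of -0.76 for the knockdown nuclear over the control whole-cell step, against -0.75 from the single-exon loci. Fragments per locus were estimated from these steps and the mean transcript length of the gene, which 80.6% of the lncRNA and 96.0% of the protein-coding loci had. The counting error of a shift follows from these fragments and covers counting only. It rests on estimated lengths.

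The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated libraries of 10140 loci in which some loci were given a known localization shift. All 50 loci at each of -2, -1.5, 1.5 and 2 were found past the threshold in the right direction, and 0.694% of the 9940 loci with no shift passed it. The shifted loci were drawn from those with a mean of at least 5 FPKM, and only counting noise was simulated. These rates therefore do not hold for low loci: draws with no shift put 20.1 of 245 lncRNA loci past the threshold. Simulated fragment steps were found within 0.954%. The alternatives tried were pseudocounts of 1 and 0.01, 3 other scalings, no filter, a minimum mean of 5 FPKM, and other definitions of the lncRNA set.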

Results

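HNRNPU is a nuclear RNA-binding protein, also known as scaffold attachment factor A, that binds chromatin and nascent RNA. The series title asks whether HNRNPU sets the nuclear localization of lncRNAs (long noncoding RNAs). RNA of K562 cells was compared between HNRNPU siRNA and control oligos in whole-cell, nuclear and cytosolic preparations, with 1 library for each of the 6 groups. Of 12824 loci with a mean of at least 1 FPKM, 10304 were protein-coding and 304 were lncRNA loci. The rest were 889 loci with clone-based names, 1010 with no name, 221 pseudogenes, 91 small RNAs and 5 of other types. Depth was uneven: 1 FPKM over 1 kilobase stood for about 13.4 fragments in the control cytosolic library and 39.2 in the knockdown nuclear library. Because no group has a replicate library, every difference below describes these libraries and has no replicate check.

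The targeted gene was lower in all 3 knockdown libraries. The HNRNPU locus (chromosome 1, 245003939 to 245027844 on hg19, merged with HNRNPU-AS1) had 129 FPKM in control and 55.3 FPKM in knockdown whole-cell RNA, so 43.0% of the control level was left. In nuclear RNA it had 163 and 63.7 FPKM (39.0% left), and in cytosolic RNA 158 and 34.9 FPKM (22.1% left). The related gene HNRNPUL1 did not share this: it had 47.7 FPKM in control and 50.4 in knockdown whole-cell RNA, 51.6 and 56.7 in nuclear RNA, and 102 and 116 in cytosolic RNA. HNRNPUL2, in a locus merged with BSCL2, had 30.9 and 35.0 FPKM in whole-cell RNA. The direction for HNRNPU was the same under every scaling and pseudocount tried.

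**Figure D1:**
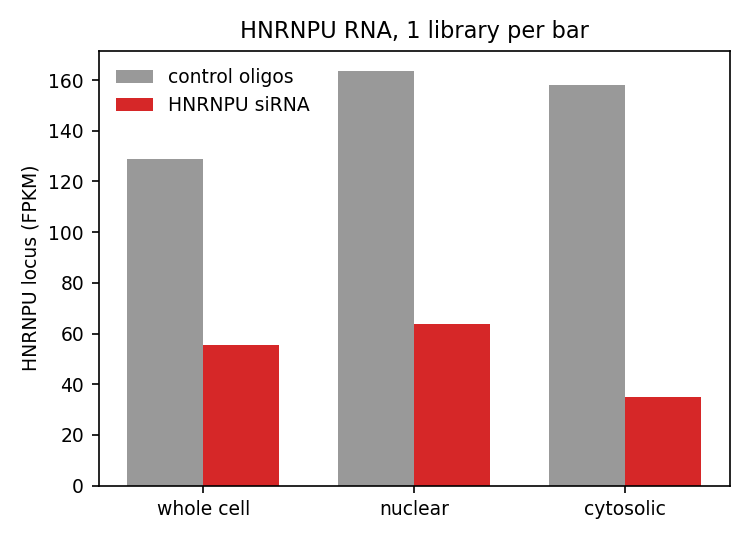
FPKM of the HNRNPU locus (vertical axis, from 0) in whole-cell, nuclear and cytosolic RNA, grey bars for control oligos and red bars for HNRNPU siRNA, each bar 1 library with no error bar. The knockdown bars stand at 55.3, 63.7 and 34.9 FPKM beside control bars at 129, 163 and 158 FPKM.

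RNAs of known location were used to check the fraction labels. MALAT1, a lncRNA of nuclear speckles, had 1984 FPKM in nuclear and 141 FPKM in cytosolic control RNA, a ratio of 14.1. NEAT1, the scaffold of paraspeckles, had a ratio of 4.87, with 67.2 and 13.7 FPKM. LINC00657 (NORAD), a cytosolic lncRNA that binds Pumilio proteins, lay the other way, with 50.9 FPKM in nuclear and 157 FPKM in cytosolic control RNA. GAS5, a small nucleolar RNA host transcript, had 240 and 853 FPKM. KCNQ1OT1, an imprinted antisense RNA, had 0.698 FPKM in nuclear and 0.0386 FPKM in cytosolic control RNA. It is below the minimum mean and was named by the fixed rule. TUG1 had 31.7 and 35.1 FPKM.

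The lists gave the same order. mRNAs of 74 ribosomal proteins had a median log2 ratio of nuclear to cytosolic RNA of -2.10 in the control and -2.03 after knockdown, against -0.61 for all protein-coding loci in both. Small nucleolar RNA loci (23) had 4.14 and 3.50. The 24 loci of the cytosolic lncRNA list had -1.58 and -1.52, and the 20 loci of the nuclear lncRNA list -0.07 and -0.40. In the control the nuclear list was at percentile 98.1 of random lists, with 9 of its 20 members above 0, and after knockdown at percentile 84.9, inside the central 95%. Transcripts with retained introns that stay in the nucleus, such as those of CLK and cyclin L genes, had a median of 0.81 in 16 loci, and 17 genes of the SR splicing factor list 0.36, both at percentile 100. The 9 mitochondrially encoded RNAs had 1.21, which places mitochondrial RNA with the nuclear preparation. mRNAs translated at the endoplasmic reticulum (30 genes of the secretory pathway) had 0.49, also at percentile 100. Absolute ratios depend on how nuclear and cytosolic libraries are scaled, so positions are given relative to protein-coding loci. Scaling to equal totals without mitochondrial and small RNAs moved the protein-coding median from -0.61 to 0.63. It also turned the nuclear lncRNA list in the control from -0.07 to 1.17.

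The question of the series is whether lncRNAs leave the nucleus when HNRNPU is low. Over the 304 lncRNA loci the median nuclear-to-cytosolic ratio was little different: the shift was -0.04 (95% interval -0.12 to 0.04), at percentile 23.1 of protein-coding lists of like mean. The median of protein-coding loci was 0.00264, so the lncRNA median centred on it was also -0.04. The best-known nuclear lncRNAs did not share a direction of shift, with MALAT1 above 0 and NEAT1 and KCNQ1OT1 below 0. The ratio for MALAT1 was 22.2 after knockdown against 14.1 in the control (shift 0.66, 13.4 times its counting error). That for NEAT1 was 4.56 against 4.87 (shift -0.10, inside the 95% range of its counting error). KCNQ1OT1 had a shift of -0.45, with cytosolic values of 0.0386 and 0.0507 FPKM. These lie below the pseudocount of 0.1, which understates its shift, and its counting error was not estimated. The 20 loci of the nuclear lncRNA list had a median shift of -0.02 (percentile 37.9), with 10 above and 10 below 0. Of them, 4 were shifted at least 2-fold to the cytosol and 0 to the nucleus: FTX (-1.88), PCAT6 (-1.80), HOTAIRM1 (-1.49) and FAM41C, which was listed at 0 in control cytosolic RNA. Shifts were 0.18 for LINC00657, 0.13 for GAS5 and 0.03 for TUG1. In cytosolic RNA alone the lncRNA loci had a median log2 ratio of knockdown to control of 0.09, at percentile 100 against 0.03 for the random lists. In nuclear RNA their median was 0.000256. Of the lncRNA loci, 139 had a higher nuclear than cytosolic FPKM by the mean of both conditions. Which loci pass this cut depends on how the libraries are scaled, and the set was not drawn under another scaling. The median shift of the 139 loci was -0.13 (95% interval -0.29 to -0.02, percentile 1.99 of lists not matched on side). Protein-coding loci picked in the same way, but not matched on level or counting error, had -0.07. Sets of them matched on counting error had -0.13 (-0.24 to 0.00259), against -0.12 for the 118 such lncRNA loci with a known length. The median shift was -0.24 for 137 lncRNA loci picked by the control alone (-0.14 for protein-coding loci, not matched). For 125 lncRNA loci picked by the knockdown alone, a set added after the data were seen, it was -0.02 (percentile 67.4). The value therefore depends on which libraries pick the set.

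A larger share of lncRNA than of protein-coding loci passed the 2-fold size rule. There were 28 lncRNA loci shifted at least 2-fold to the cytosol (9.21%) and 16 shifted at least 2-fold to the nucleus (5.26%). Among protein-coding loci there were 152 (1.48%) and 115 (1.12%). Random protein-coding lists of like mean held 13 shifted to the cytosol (7 to 21 in the central 95%) and 10 shifted to the nucleus (5 to 17). Matched on counting error instead, they held 30.4 shifted either way (21 to 40), against 36 of the 245 lncRNA loci with a known length. Each count moved by more than 1.5 times with a pseudocount of 1, with no filter and with a minimum mean of 5 FPKM, for lncRNA and protein-coding loci alike. At a minimum mean of 5 FPKM, 4 of 117 lncRNA loci were shifted to the cytosol and 1 to the nucleus.

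Of the 8 lncRNA loci with the lowest shifts, 4 had values above 0 in each fraction library, and FTX had the smallest counting error of these. It is a transcript of the X-inactivation center (chromosome X, 73183789 to 73513409 on hg19). It had 9.97 FPKM in control and 8.25 FPKM in knockdown nuclear RNA, and 0.444 and 1.55 FPKM in cytosolic RNA. Its ratio of nuclear to cytosolic RNA, with the pseudocount, was 18.5 in the control and 5.05 after knockdown, a shift of -1.88. About 711 and 1184 fragments supported the nuclear values of FTX and 21.8 and 84.5 the cytosolic ones, so the shift was 6.51 times its counting error. HCG27, in the major histocompatibility region, had 2.66 and 1.92 FPKM in nuclear RNA and 0.0494 and 0.676 in cytosolic RNA (shift -2.83), from about 0.619 and 9.38 cytosolic fragments. LAMTOR5-AS1 had 0.915 and 2.61 FPKM in cytosolic RNA (shift -1.97), and SNHG9, a snoRNA host gene, 0.309 and 3.04 FPKM (shift -2.47). The cytosolic values of SNHG9 rest on about 0.634 and 6.91 fragments, and its shift lay inside the 95% range of its counting error.

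LINC00508, LINC01037, ZRANB2-AS1 and the ANKRD62P1-PARP4P3 locus complete that end and were listed at 0 in control cytosolic RNA, so no fold is given. The last is a merged locus that also carries the names ANKRD62P1, PARP4P3, VWFP1 and KB-7G2.8. LINC00508 had 53.6 FPKM in knockdown cytosolic RNA beside 11.1 and 4.63 FPKM in nuclear RNA, and was listed at 0 in knockdown whole-cell RNA too. LINC01037 had 4.64, ZRANB2-AS1 0.625 and ANKRD62P1-PARP4P3 0.180 FPKM in knockdown cytosolic RNA.

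At the other end, LENG8-AS1 had 4.27 FPKM in control and 1.22 FPKM in knockdown cytosolic RNA, beside 5.70 and 7.84 FPKM in nuclear RNA (shift 2.19). TPT1-AS1 had cytosolic values of 3.25 and 1.12 FPKM (shift 1.80), STXBP5-AS1 2.14 and 0.644 FPKM (shift 1.66), and SOS1-IT1 1.26 and 0.331 FPKM (shift 1.87). MFI2-AS1 had the highest shift of the lncRNA loci, 3.15, with 1.15 and 0.0925 FPKM in cytosolic RNA, and TM4SF19-AS1 had 2.75, from about 9.58 and 1.21 cytosolic fragments. CHKB-AS1 was listed at 0 in control nuclear RNA and had 0.585 FPKM after knockdown. ACAP2-IT1 was listed at 0 in knockdown cytosolic RNA and had 0.322 FPKM in the control. Most of these names are antisense or intronic transcripts of coding genes, and fragments of those genes could have been counted there. For the antisense ones this depends on whether counting used the strand, which is not given.

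**Figure D2:**
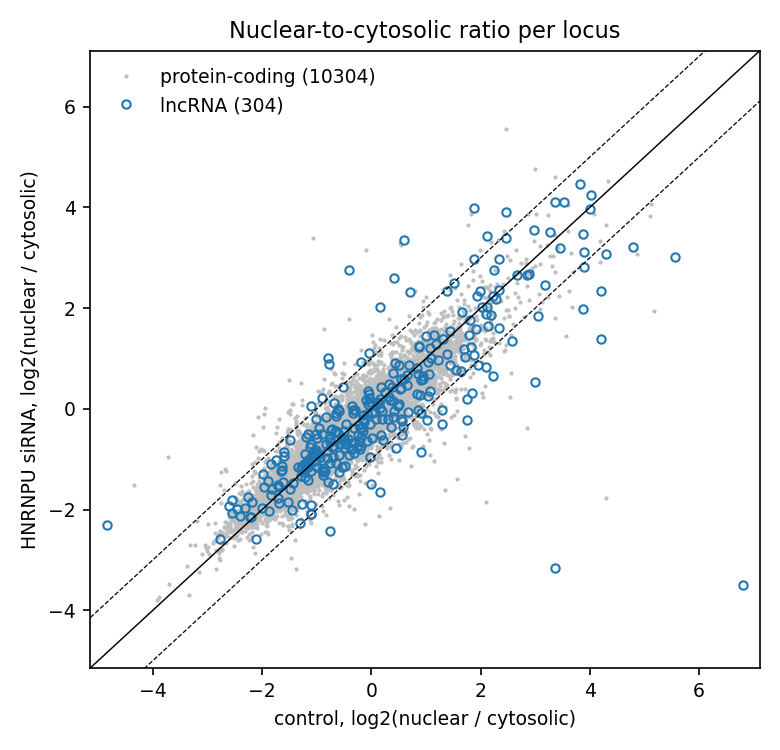
Log2 ratio of nuclear to cytosolic FPKM per locus in the control (horizontal axis) and after HNRNPU siRNA (vertical axis), grey points for 10304 protein-coding loci and blue circles for 304 lncRNA loci; the solid line marks equal ratios and the dashed lines a shift of 1 either way. Of the lncRNA loci, 28 lie on or below the lower dashed line and 16 on or above the upper one.

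Depth limits what single lncRNA loci can show. The median lncRNA locus had about 30.7 fragments in the shallowest of its 4 fraction libraries, and the median protein-coding locus 223. The estimated counting error of the shift was 0.40 log2 units for the median lncRNA locus and 0.16 for the median protein-coding locus. Of the 24 lncRNA loci with a known length shifted at least 2-fold to the cytosol, 15 lay beyond the 95% range of their counting error, and of the 12 shifted to the nucleus, 5 did. Of protein-coding loci, 122 of 145 and 95 of 112 did. Protein-coding loci held 257 shifted either way, against 53.6 (41 to 68) in Poisson draws with no shift. Passing the counting error was common among protein-coding loci picked for a 2-fold shift. A shift of that size lies far beyond the counting error of most of them, so this was largely set by the pick. The share of all loci that passed it is not given here. Across loci, Pearson's r of the nuclear-to-cytosolic ratio between control and knockdown was 0.79 for lncRNA and 0.91 for protein-coding loci, where loci are not independent replicates.

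**Figure D3:**
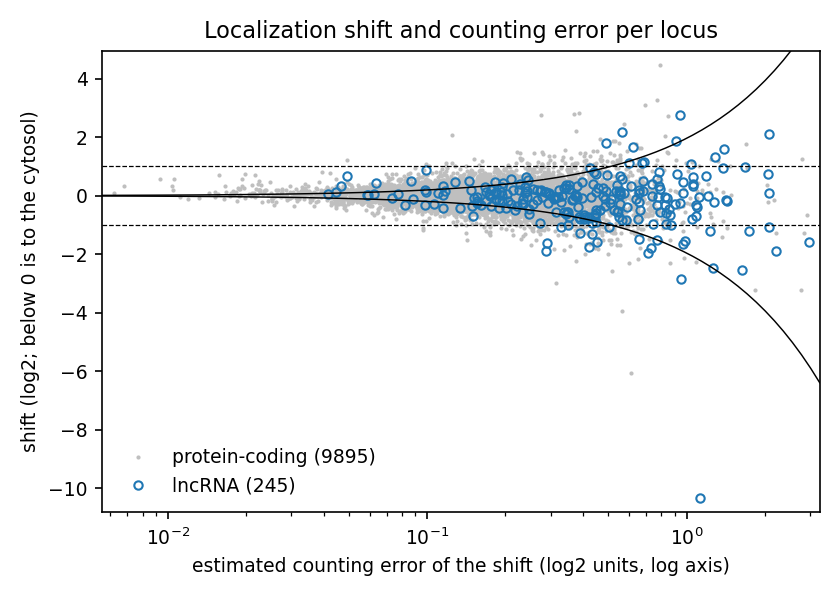
Localization shift (vertical axis, log2; below 0 is to the cytosol) against its estimated counting error (horizontal axis, log scale, log2 units) for 9895 protein-coding loci (grey) and 245 lncRNA loci (blue) with a known length; curves mark the 95% range of the counting error and dashed lines a shift of 1 either way. Shifted lncRNA loci lie mostly at high counting error, where the median over lncRNA loci is 0.40.

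Among protein-coding genes with a mean of at least 5 FPKM, the lowest shifts came from higher cytosolic levels, lower nuclear levels or both. VPS9D1 had 8.92 FPKM in control and 34.1 FPKM in knockdown cytosolic RNA (shift -1.81) and IGF1R, the insulin-like growth factor receptor, 2.47 and 5.45 FPKM (shift -1.29). Whole-cell RNA did not share these differences, with 3.29 and 3.92 FPKM for VPS9D1 and 8.86 and 6.87 FPKM for IGF1R. DLC1, a gene with a role in cell adhesion and the cytoskeleton, had 10.6 and 18.5 FPKM in cytosolic and 15.1 and 9.08 FPKM in nuclear RNA (shift -1.52). NUMBL, related to the Notch regulator NUMB, had log2 ratios of knockdown to control of -0.92 in nuclear and 0.55 in cytosolic RNA (shift -1.47), and HELZ2, a helicase, -0.89 and 0.47 (shift -1.35). The highest shift was that of TTLL7, a tubulin glutamylase, with 1.97 and 21.7 FPKM in nuclear RNA and 1.35 and 2.12 FPKM in cytosolic RNA (shift 2.78). TTLL7 passed the minimum, with a mean of 5.12 FPKM, only through its knockdown nuclear library. Whole-cell RNA had 1.32 and 2.28 FPKM of it. LCORL, a transcription factor, had 11.5 and 3.72 FPKM in cytosolic RNA (shift 2.08), and ZNF584, a zinc finger gene, 2.54 and 6.64 FPKM in nuclear RNA (shift 1.47). CDKL1, a cyclin-dependent kinase-like gene, had a shift of 1.42. The merged locus of LCNL1 and PTGDS had 23.3 and 2.78 FPKM in cytosolic RNA (shift 2.76), but 13.6 and 33.9 FPKM in whole-cell RNA.

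Whole-cell RNA shows whether HNRNPU knockdown went with other RNA levels. Protein-coding loci had a median log2 ratio of knockdown to control of 0.07, and 67 protein-coding or lncRNA loci were at least 2-fold higher and 57 at least 2-fold lower after knockdown. With each library scaled to the protein-coding median these were 59 and 76, and with equal totals without mitochondrial and small RNAs 63 and 81, so which direction held more loci depends on the scaling. Both counts also moved by more than 1.5 times with a pseudocount of 1, quantile normalization, no filter and a minimum mean of 5 FPKM, where 20 and 12 loci were left.

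The clearest genes were those at least 1.5-fold apart in the same direction in all 3 preparations, a count added after the data were seen: 9 were higher and 8 lower among 8117 loci with a mean of at least 5 FPKM. TXNIP, an inhibitor of thioredoxin that also limits glucose uptake, had 47.7 FPKM in control and 132 FPKM in knockdown whole-cell RNA, 72.3 and 215 FPKM in nuclear RNA and 69.5 and 173 FPKM in cytosolic RNA. ARRDC4, an arrestin-domain relative of TXNIP, had log2 ratios of 1.04, 0.96 and 0.82 in the same order. KLF10, a transcription factor of the TGF-beta response, had 1.25, 1.32 and 1.19. COX20, an assembly factor of cytochrome c oxidase, had 1.33 in whole-cell and 0.97 in cytosolic RNA, and 3.29 and 7.19 FPKM in nuclear RNA. Its locus (chromosome 1, 244998623 to 245008359 on hg19) overlaps that of HNRNPU. TPM4, a tropomyosin, had 0.89, 0.74 and 1.01, and ATG10, an autophagy gene, 0.82, 0.88 and 0.65. TTLL7, which passed the minimum mean only through its knockdown nuclear library, had 0.75, 3.39 and 0.62. The lncRNA ZNF385D-AS1 (0.65, 1.05 and 0.95) was higher too.

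Lower in all 3 preparations, beside HNRNPU itself, were NLRP1, LMAN2, HBA2, GDPD5, IL16, HNRNPD and HBA1. NLRP1, an inflammasome sensor, had log2 ratios of -1.41 in whole-cell, -1.78 in nuclear and -0.95 in cytosolic RNA. LMAN2, a cargo lectin between endoplasmic reticulum and Golgi, had 79.9 and 36.8 FPKM in whole-cell RNA and log2 ratios of -1.12, -1.24 and -1.04. HNRNPD, which binds AU-rich elements, had -0.69, -0.62 and -0.68. IL16, a cytokine gene, had -0.71, -1.08 and -0.76, and GDPD5 -0.72, -0.78 and -0.80. The alpha-globin genes HBA1 and HBA2, near-identical copies whose fragments the counting could split either way, had -0.61 and -0.83 in whole-cell RNA.

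**Figure D4:**
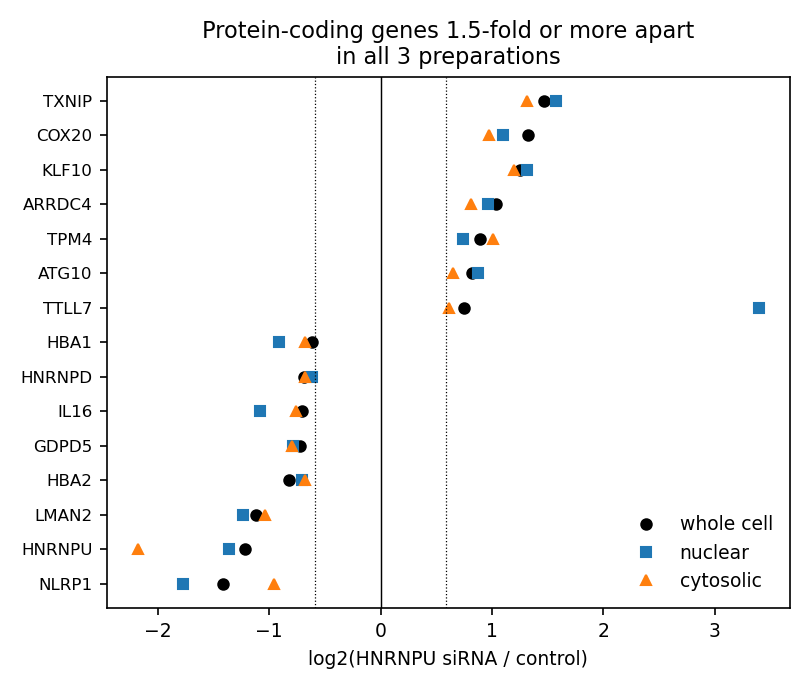
Log2 ratio of HNRNPU siRNA to control (horizontal axis) in whole-cell (circles), nuclear (squares) and cytosolic RNA (triangles) for the protein-coding genes at least 1.5-fold apart in the same direction in all 3 preparations; each point is 1 pair of libraries with no error, and dotted lines mark 1.5-fold. TTLL7 reached 3.39 in nuclear RNA, and HNRNPU lay at -2.18 in cytosolic RNA.

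Other genes named for whole-cell RNA had smaller ratios in the fractions. CDKL1 was the highest, with 2.30 FPKM in control and 25.1 FPKM in knockdown whole-cell RNA (log2 ratio 3.39), beside 1.83 in nuclear and 0.41 in cytosolic RNA. RGS19, a regulator of G protein signaling, had 1.52, 0.18 and 1.05. PLCD3, a phospholipase C, had 1.30 in whole-cell RNA and 0.02 and 0.12 in the fractions, TRIM35 1.26, 0.04 and 0.11, and the merged locus of SARM1 and TMEM199 1.27, 0.34 and 0.28. At the lower end SMIM4 had -1.33, -0.49 and -0.20. NTAN1 had -0.94, HHLA3 -0.90 and LTBP3, which binds latent TGF-beta, -0.87 in whole-cell RNA. Of the lncRNAs, LINC00339 (0.74) and LINC00963 (0.52) were higher, and CT49 (-0.79), LINC01033 (-0.53), LINC00520 (-0.51) and TMEM161B-AS1 (-0.32) were lower. Across the 8117 loci, the whole-cell ratios had a Spearman correlation of 0.25 with the nuclear and 0.25 with the cytosolic ratios.

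Of 140 medians (35 lists with at least 3 measured loci, in 3 preparations and as shifts), 26 lay outside the central 95% of random lists. For lists of unrelated loci 7 would. Members of a list can vary together, which random lists do not reproduce, so 26 against 7 is not a count of changed lists. The erythroid list was lower in all 3 preparations, with medians of -0.08 in whole-cell (percentile 0.08), -0.08 in nuclear (percentile 1.79) and -0.09 in cytosolic RNA (percentile 0.56) over 26 genes. K562 cells express globins and other erythroid genes. In whole-cell RNA 17 of the 26 were below 0, RHCE (-0.96), HBA2 (-0.83), HBA1 (-0.61) and HEMGN (-0.43) furthest. The fetal globin gene HBG1, named after its value was seen, was at 0.30 there. The interferon list was lower in whole-cell RNA (median -0.19, percentile 0.68, 7 of 12 genes below 0), with IFI27 at -0.89 and OAS3 at -0.72, while DDX58 was at 0.58. Megakaryocytic genes were lower in nuclear RNA (median -0.27 over 9 genes, percentile 1.80), with ITGA2B at -0.77. The 17 SR splicing factor genes had a whole-cell median of -0.02 (percentile 2.05), with TRA2A at -0.28 and SRSF10 at 0.31.

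Genes of the U2 spliceosomal particle were higher in whole-cell RNA, with a median of 0.22 over 17 genes (percentile 99.6), 15 of them above 0, SF3A1 (0.57) and SNRPB2 (0.48) furthest. Mitochondrial ribosome genes were higher in whole-cell (0.15, percentile 99.7) and nuclear RNA (0.12, percentile 98.1), with MRPL40 at 0.52 in whole-cell RNA and MRPS27 at -0.60. Histone loci (49, multi-copy genes with like sequences) had medians of 0.17 in whole-cell and 0.16 in cytosolic RNA, each at percentile 100, but -0.02 in nuclear RNA (percentile 1.90), so their shift was -0.19. HIST1H3E, a low locus with 0.757 and 1.63 FPKM in whole-cell RNA, was highest (1.01) and HIST1H4A lowest (-0.71). HIST1H2AB had 26.2 and 39.8 FPKM and HIST2H2AC 225 and 337 FPKM. Translation factor genes had a shift of 0.14 (31 genes, percentile 99.7) and a nuclear median of 0.16, with EIF3L shifted by 0.48 and EIF3H by 0.42. Ribosomal protein genes were at -0.04 in cytosolic RNA (percentile 0.09). Quantile normalization put that median at 0. Nuclear export genes were at 0.17 in nuclear RNA (percentile 97.7), RNA exosome genes at 0.18 in cytosolic RNA (percentile 98.4), and 286 zinc finger loci at 0.10 in nuclear and 0.08 in cytosolic RNA (percentiles 100 and 98.7). The cytosolic lncRNA list was at 0.01 in whole-cell RNA (percentile 1.73), a sign that each of the 3 other scalings turned. Some of these medians lay inside the range of random lists under another setting. With quantile normalization these were the cytosolic lncRNA list, ribosomal protein genes, nuclear histone RNA, and translation factor genes in nuclear RNA (0.10) and as a shift (0.07). With no filter they were the SR and cytosolic lncRNA lists, nuclear histone RNA, mitochondrial ribosome genes in whole-cell RNA (0.12) and nuclear export genes. At a mean of at least 5 FPKM they were the cytosolic lncRNA list and the interferon list (-0.03).

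The mitochondrially encoded RNAs stood apart as a group. Their median log2 ratio of knockdown to control was 0.41 in nuclear RNA (percentile 100, 9 of 9 loci above 0), -0.07 in cytosolic and -0.01 in whole-cell RNA, which makes a shift of 0.50. MT-CYB was furthest in nuclear RNA, with 1667 FPKM in control and 2522 FPKM after knockdown. MT-ND3 had the highest shift (0.77) and MT-RNR1, at a low level, the lowest (-1.20). Quantile normalization, which gives the top ranks of each library the same values, put the nuclear median at 0 and the shift at 0.03, inside the range of random lists. Small nuclear RNA loci (22, many of them copies with like sequences) had a nuclear median of -1.33 and a shift of -1.28, both at percentile 0, and small nucleolar RNA loci a nuclear median of 0.16 (percentile 97.9). Many of these are listed at 0 in some libraries, and fragments of near-identical copies could have been assigned to any of them.

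Of the lists with no median outside that range in any preparation, the hnRNP list had a whole-cell median of 0.04 over 21 genes, in which HNRNPD (-0.69) was lowest and HNRNPH3 (0.44) highest. The 34 cell cycle genes had 0.04, 24 ATF4 stress genes 0.09, 15 heat shock genes 0.08 and 22 apoptosis genes 0.01. The 3 other scalings each turned the sign of the hnRNP, cell cycle and apoptosis medians, and quantile normalization that of the heat shock median. Markers of other cell types gave few measured loci: 3 lymphoid genes had a whole-cell median of -0.22, 6 myeloid genes 0.06 (below 0 under the 3 other scalings) and 7 epithelial or stromal genes 0.14.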

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

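This part reports no tests, and its 1.5-fold minimum was set after the data were seen. DLC1, a gene with a role in cell adhesion and the cytoskeleton, was picked out because its nuclear and cytosolic levels differed in opposite directions between knockdown and control, each by at least 1.5-fold. Its log2 ratio of knockdown to control was -0.73 in nuclear and 0.79 in cytosolic RNA, a shift of -1.52, with -0.13 in whole-cell RNA. The difference was not tested, since each group has 1 library. Of 57 named loci it was the 1 that met this rule, with 2 more left out because a fraction library listed them at 0.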

How the results depend on the processing

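The tests with clone-named loci, with single gene names and with a fragment minimum, and those of genes apart in all 3 preparations, were chosen after seeing the data. Of 172 comparisons of a main result with an alternative setting, 134 stayed the same, 35 moved and 3 reversed. Of 490 comparisons for named genes 454 stayed the same, 36 moved and none reversed. For these genes a reversal counts only for a log2 value of at least 1 either way. A smaller value that turned sign counted as the same if it stayed within 1.5-fold of the main one. Of 976 for gene lists, 915 stayed the same, 57 moved and 4 reversed, where a reversal counts only for a median outside the range of random lists. Of all 140 list medians, at least 1 of the 3 other scalings turned the sign of 47, most of them close to 0. The causes were not tested, except that a filter or a larger pseudocount acts on low loci by construction. HNRNPU kept its direction in all 3 preparations under the 2 other pseudocounts and 3 other scalings. The nuclear lncRNA list in the control, at -0.07, went to 0.52 with the protein-coding median scaling, 1.17 with equal totals and 0.10 with no filter. The cytosolic lncRNA list went to -0.33 in the control and -0.31 after knockdown with equal totals, and to -0.29 after knockdown with quantile normalization. The ribosomal protein list in the control went to -1.49, -0.85 and -0.50 with the protein-coding median, equal totals and quantile normalization, and after knockdown to -1.41, -0.82 and -0.50. In whole-cell RNA the cytosolic lncRNA list turned to -0.0636, -0.0600 and -0.0377 under these scalings, and the SR list to 0.00196 with no filter. The lncRNA shift was -0.13 for loci of higher nuclear than cytosolic FPKM by the mean of both conditions and -0.24 for those by the control. Counts of lncRNA loci shifted to the cytosol were 13 with a pseudocount of 1, 130 with no filter, 4 at a mean of 5 FPKM, 151 with clone-named loci and 14 with at least 100 estimated fragments. Those shifted to the nucleus were 4, 120, 1, 116 and 5. Protein-coding loci shifted to the cytosol were 47, 822 and 31 under the first 3 of these and 35, 659 and 23 to the nucleus. With lncRNA loci picked by the form of the symbol (250), 18 were shifted to the cytosol and 13 to the nucleus. Whole-cell loci at least 2-fold higher were 22 with a pseudocount of 1, 109 with quantile normalization, 437 with no filter and 20 at a mean of 5 FPKM, and lower ones 11, 107, 511 and 12. Of the 26 list medians outside the range of random lists, 19 stayed outside with quantile normalization, 21 with no filter and 24 at a mean of 5 FPKM, and 26 with each other pseudocount and each of the 2 other scalings. The share of lncRNA loci shifted to the cytosol was above that of protein-coding loci in each of these settings, 3.42% against 0.388% at a mean of 5 FPKM and 12.8% against 5.28% with no filter. Depth limits the low loci most: a lncRNA locus had a median of 30.7 fragments in its shallowest fraction library. No replicate could be left out, since each group has 1 library, and settings that need read counts were not run. No paired analysis was possible within a preparation because each has 1 control and 1 knockdown library, and one that takes the 3 preparations as pairs was not run.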

Other observations

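The tests of the mitochondrial RNAs, of COX20, of the excess to the cytosol against protein-coding loci of like counting error and of the nuclear lncRNA loci were chosen only after the results were seen. Loci without a gene name were far more nuclear than protein-coding or lncRNA loci: 1010 of them had a median log2 ratio of nuclear to cytosolic RNA of 2.94 in the control and 3.01 after knockdown. Their median shift was 0.07, and they were not matched on counting error with other loci. Among them 129 were shifted at least 2-fold to the cytosol and 157 to the nucleus. Loci with clone-based names had 123 and 100. The list of nuclear matrix and paraspeckle genes (16) had a median ratio of -0.07 in the control at percentile 99.8, so their mRNAs were more nuclear than those of genes of like level.

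Of 245 lncRNA loci with a known length 36 were shifted at least 2-fold between fractions, with an excess of 12 to the cytosol. Poisson draws with no shift held 20.1 (13 to 27) and an excess of 0.704 (-7 to 9), which argues against counting noise alone. The counts each way were closer with quantile normalization, at 7.24% of 304 lncRNA loci to the cytosol and 5.59% to the nucleus. They were also closer for lncRNA loci picked by the form of the symbol, at 18 and 13 of 250. Neither setting was compared with draws. With fragments fewer by 2 times, draws held as many shifted loci (39.0, 29 to 48), and the 24 loci to the cytosol lay inside (12 to 27). The excess of 12 lay just outside (-13 to 11), because the 12 loci to the nucleus fell below the draws (13 to 28). Protein-coding loci of like counting error held 30.4 shifted loci (21 to 40) and an excess of 3.70 (-7 to 14), so over all lncRNA loci neither value sets them apart. The 118 nuclear lncRNA loci, those of higher nuclear than cytosolic FPKM, had 32 shifted and 21 to the cytosol. Both counts lay above sets of all protein-coding loci of like counting error (19.8, 12 to 28, and 5 to 18 to the cytosol). The median counting error of those sets was lower, at 0.51 against 0.55. Against nuclear protein-coding loci of like counting error both lay inside, 21 at the upper bound (24.7, 17 to 33, and 14.4, 8 to 21). The excess of 10 to the cytosol lay inside both comparisons (-6 to 11 and -5 to 14). The median shift of the nuclear protein-coding sets was -0.13, against -0.12 for the lncRNA loci. FTX was shifted to the cytosol by 6.51 counting errors and MALAT1 to the nucleus by 13.4, and whether any single shift came from HNRNPU or from variation between cultures or fractionations was not tested, since each group has 1 library.

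Mitochondrially encoded RNAs were higher in nuclear RNA after knockdown in 9 of 9 loci, while in cytosolic RNA 5 were lower and 4 higher, with a median of -0.07 inside the range of random lists. Quantile normalization put their shift at 0.03, against 0.50, while the 2 other scalings gave 0.51 and 0.45. A different mitochondrial RNA level was not seen in whole-cell RNA, with a median of -0.0127. Whether that RNA came from the same culture as the nuclear RNA is not given, so this cannot exclude such a level in the fractionated cells. More membrane of every kind in the nuclear preparation is argued against by the shift of -0.0238 of the secretory mRNAs. A larger share of mitochondria alone in the knockdown nuclear preparation needs a like shift of every mitochondrial mRNA. Of the 8 loci 7 had a shift above 0, over a range from -0.33 to 0.77, and the ribosomal RNA locus MT-RNR1 had -1.20 at a low level, so this stays open.

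The genes at least 1.5-fold apart in all 3 preparations were too many for chance agreement between unrelated preparations: 9 higher and 8 lower were found, and the highest count in 10000 permutations among loci of like mean was 2. This does not separate an effect of the siRNA from a difference between cultures, because the preparations may share a culture. The 8 lower genes include HNRNPU, the target of the siRNA, and the near-identical HBA1 and HBA2, so they are not 8 independent results. COX20 overlaps HNRNPU, so HNRNPU fragments counted there would make COX20 lower after knockdown, but its lowest log2 ratio in the 3 preparations was 0.97. No other cause was tested for COX20.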
